A study of Caenorhabditis elegans with 4 samples.

How the data were processed

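Chromatin immunoprecipitation followed by sequencing was done on C. elegans embryos of strain OP186, in which UNC-39 carries a GFP tag. GEO's labels describe 2 ChIP samples and 2 input samples, numbered 1 and 2 in their titles. Groups were taken from the titles and source names. The description field disagrees with the titles: it names the antibody on the input samples and calls the ChIP samples input DNA. The region lists belong to the samples whose titles say ChIP.

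The authors deposited 1 list of binding regions for each ChIP replicate and 1 combined list. The deposited value of each region is a q-value from the peak caller PeakSeq, per the source and attribute columns of the files. The build is WormBase WS180, per the file headers. The PeakSeq version and settings, the aligner, the control used, the q threshold and the way in which the combined list was made are not given in the sources used here. Regions in the lists do not overlap each other, and the largest q was 4.2e-05 in replicate 1 and 5.37e-05 in replicate 2 and in the combined list. Of the combined regions, 44 were narrower than 50 bp and the narrowest was 1 bp. The lists hold no read counts, so depth is unknown and the precision of a single q cannot be given. A q-value depends on depth as well as on occupancy, so q was compared by rank or as −log10 q between the lists and never as a level of binding.

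The remaining steps were computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Regions were ranked by q, from the smallest. The words stronger, strongest and strength refer to q or this rank, not to a level of binding. Regions of different lists were taken as shared with an overlap of at least 1 bp. The overlap was tested against 10000 random placements of the regions, with their widths and chromosomes kept, between the first and the last position of any region on that chromosome. This span stood in for the chromosome length, since no WS180 sequence was at hand; the spans sum to 98.8 Mb. Ranks of shared and unshared regions were compared by permutation with 100000 resamples, or by an exact rank-sum permutation test where a group had fewer than 10 regions. Correlations had permutation p-values from 100000 resamples. Counts per chromosome were tested with the exact binomial test against the share of the span and adjusted by Benjamini-Hochberg over 6 chromosomes, with a threshold of 0.05. Each span was also divided into 3 equal parts to test the middle part. Intervals are 95% Wilson intervals.

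The tests were tested on simulated data first. With unrelated lists of 318 regions, 3% of 100 simulated overlap tests passed the threshold. These lists were placed by the same random rule as in the test, so this does not cover lists whose regions cluster. All 50 planted shared regions were found in each simulation. Each was planted at the start of a replicate 2 region, so this outcome was fixed and checks the code only. In lists of 1082 regions, an excess planted on chromosome I was called in 100% of 100 simulations, and in 1% without an excess. These regions were drawn independently of each other. The planted excess was larger than those reported on III and X in the combined list, and smaller ones were not simulated. With no effect, the median difference was called in 5% of 200 simulations, and the exact rank-sum test and the Spearman correlation in 4.5% each.

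The planned tests and alternatives, the gene lists and the rule for naming were fixed before the data were examined. The plan named the authors' score and the chromosome length; the use of q as the score and of the span as the length was settled once the lists were seen, as were the exact rank-sum test and the Fisher's exact test of chromosome I. The rule named the 20 strongest combined regions found in both replicate lists, the 5 strongest of each replicate list, the listed genes with a region, and unc-39 itself. A share of these is given with coordinates. The widest region and the runs of close regions were chosen after their values were seen. For 3 planned results there is no value: the share of regions near a transcript start, the test of 16 gene lists, and the share of regions with a motif of the protein family. They need a WS180 annotation or genome, which was not at hand. The gene table used here is on assembly WBcel235, so its coordinates were not set against WS180 regions, and unc-39 has no value for the same reason. That table served only to count protein-coding genes per chromosome, as an alternative expectation, and to look up the chromosome of unc-39.

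The alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, the regions stronger than the median of a list, as many top replicate 2 regions as replicate 1 has, a circular shift, each replicate list in place of the combined list, the regions in both lists, and expectation from gene number. After the data were seen, regions of at least 50 bp and windows with identical lists were added.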

Results

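The series mapped where UNC-39 bound the genome of Caenorhabditis elegans embryos. UNC-39 is a homeodomain transcription factor, known from genetic work to act in mesoderm and in neurons. The animals carried an unc-39 transgene that ends in a GFP and FLAG tag (strain OP186) and were grown at 20 °C. Chromatin was crosslinked with 2% formaldehyde and precipitated with a goat antibody against GFP. The samples were 2 ChIP replicates and 2 input controls of total chromatin DNA. Binding regions were available as 1 list for each ChIP replicate and 1 combined list; no values of the inputs were analysed here. All coordinates are on WormBase WS180. The lists give positions and a q-value for each region but no gene names and no read counts, so the sequencing depth behind each q is unknown. Whether a region lies in a promoter, exon or intron was not analysed here, since no WS180 annotation was at hand.

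The combined list held 1082 regions that covered 537 kb, at 10.96 regions per Mb. Their median width was 376 bp, with quartiles at 245 and 588 bp. The q-values ran from 3.02e-64 to 5.37e-05. Replicate 2 gave 1077 regions covering 534 kb and replicate 1 gave 318 regions covering 170 kb, so the replicate 2 list was 3.39 times as long. Median widths were close, at 375 bp in replicate 2 and 368 bp in replicate 1. The smallest q was 3.02e-64 in replicate 2 and 8.13e-32 in replicate 1.

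The strongest UNC-39 regions were found in both replicate lists. The first lay on chromosome IV from 14032438 to 14034628, with q = 3.02e-64 in the combined list and q = 2.88e-31 in replicate 1, where it ranked 2. The next lay on chromosome X from 11605358 to 11606507, with q = 5.74e-57, and was the strongest region of replicate 1, where its span was 11605642 to 11606471 and its q was 8.13e-32. A narrow region of 360 bp on chromosome IV, 7486210 to 7486569, ranked 3 in each of the lists, with q = 7.56e-37 in the combined list and 1.02e-21 in replicate 1. The region on chromosome V from 9342982 to 9344566 had q = 1.66e-35 in the combined list and ranked 19 in replicate 1. On chromosome I the regions 4171991 to 4172641 (q = 4.12e-34) and 9988608 to 9989155 (q = 5.81e-34) ranked 5 and 6, and they ranked 4 and 7 in replicate 1. The region on chromosome III from 10461016 to 10461430 had q = 1.42e-31 and ranked 8 in replicate 1. The region on chromosome X from 12691504 to 12693615 had q = 1.2e-30 and ranked 6 there. The region on chromosome IV from 13029285 to 13030417 ranked 11 in the combined list and 5 in replicate 1.

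All of the top 20 combined regions overlapped a region in both replicate lists. Of these, 6 lay on chromosome X, 4 on IV, 4 on V, 3 on I, 2 on III and 1 on II. Their median width was 1097 bp. A single region was far wider than any other: it ran on chromosome V from 14364428 to 14388185, a width of 23758 bp, against 4788 bp for the next widest region of the combined list. It ranked 13 in the combined list (q = 7.45e-28) and 50 in replicate 1 (q = 5.2e-10), where its width was 23718 bp. The inputs, which would show extra copies of this DNA, were not analysed here. Ranks of lists of different lengths show no change in binding. The highest rank number in replicate 1 among the 20 was that of a region of 3054 bp on chromosome I, 1834253 to 1837306, which ranked 18 in the combined list (q = 2.44e-24) and 222 of 318 in replicate 1 (q = 7.82e-06).

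The first comparison asked whether the separate replicates gave the same regions. Nearly all replicate 1 regions were also called in replicate 2. With an overlap of at least 1 bp, 311 of 318 replicate 1 regions met a replicate 2 region, or 97.8% (95% Wilson interval 95.5 to 98.9%). Random placement of the replicate 1 regions on the same chromosomes gave a mean of 3.57 overlaps and at most 15 (one-sided permutation test, 10000 placements, p = 0.0001, the smallest these placements can give). In the other direction, 310 of 1077 replicate 2 regions met a replicate 1 region, or 28.8% (26.2 to 31.6%). The 7 replicate 1 regions without a partner comprised 4 on chromosome III, 2 on IV and 1 on II. Their q-values began at 2.67e-06 and their ranks lay between 187 and 306 of 318. Nothing in the labels says that the replicates came from separate cultures, and intervals here cover counting error only. Whether the replicate 2 list drew on reads of replicate 1 cannot be told from the lists, and the overlap is independent evidence only if it did not.

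Regions shared by the replicates were the stronger ones by q. Within the replicate 2 list, shared regions had a median percentile of 83.9 by q and unshared regions of 36.1, where 100 is the smallest q (difference 47.8, two-sided permutation test with 100000 resamples, p = 1e-05, the smallest these resamples can give). The median width in replicate 2 was 458 bp for shared and 343 bp for unshared regions, while in replicate 1 it was 367 bp for shared and 645 bp for the 7 unshared regions; widths were not tested. The replicate 2 list was also split by q into 5 classes of near equal size. In the strongest class, 185 of 216 regions (85.6%) were found in replicate 1, and the share was 38.1%, 15.8%, 2.33% and 1.85% in the classes that followed. Within the replicate 1 list the 311 shared regions had a median percentile of 51.1 and the 7 unshared regions of 34.4 (exact two-sided rank-sum permutation test, p = 0.0233). Of the 10 strongest replicate 1 regions, 8 overlapped one of the 10 strongest of replicate 2, and 77 of the top 100 overlapped one of the other top 100.

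The order of strength was similar in both lists. Over the 311 overlapping pairs, −log10 q correlated with Spearman's rho = 0.76 and Pearson's r = 0.88 (two-sided permutation tests, p = 1e-05 for each, the smallest possible). Pearson's r was 0.83 without the 2 pairs farthest from the median of replicate 1. This correlation is across regions, which are not independent replicates. If the replicate 2 list drew on reads of replicate 1, the correlation and the ranks of shared regions compare replicate 1 partly with itself. The q was smaller in replicate 2 for 304 of the 311 pairs. The median −log10 q was 9.96 in replicate 2 and 5.93 in replicate 1.

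**Figure D1:**
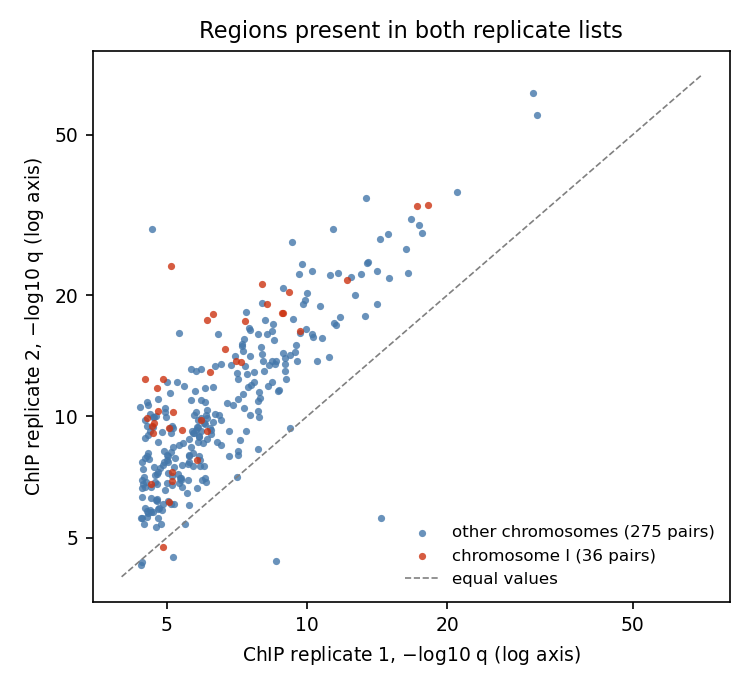
Strength of the regions present in both replicate lists: −log10 q in ChIP replicate 1 (x, log axis) against ChIP replicate 2 (y, log axis), 1 point for each of 311 overlapping pairs, with chromosome I in red and the others in blue. Of the 311 pairs, 304 lie above the dashed line of equal values.

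The combined list was close to the replicate 2 list, row for row. Of its 1082 regions, 884 (81.7%) had the same start, end and q as a replicate 2 region, and 1 had the start and end of a replicate 1 region. Overlap with a replicate 2 region was found for 1065 combined regions and with a replicate 1 region for 309. Both lists were met by 309 regions (28.6%, 25.9 to 31.3%), replicate 2 alone by 756, replicate 1 alone by 0 and neither by 17. Among the 541 strongest combined regions, the share met by both lists was 52.7%. The regions met by both lists had a median −log10 q of 9.95 in the combined list, those met by replicate 2 alone of 5.31, and those met by neither of 4.54. Conversely, 12 replicate 2 regions and 8 replicate 1 regions were missing from the combined list. The combined list was therefore not an independent measurement beside replicate 2, and how it was combined is not given in the sources used here.

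**Figure D2:**
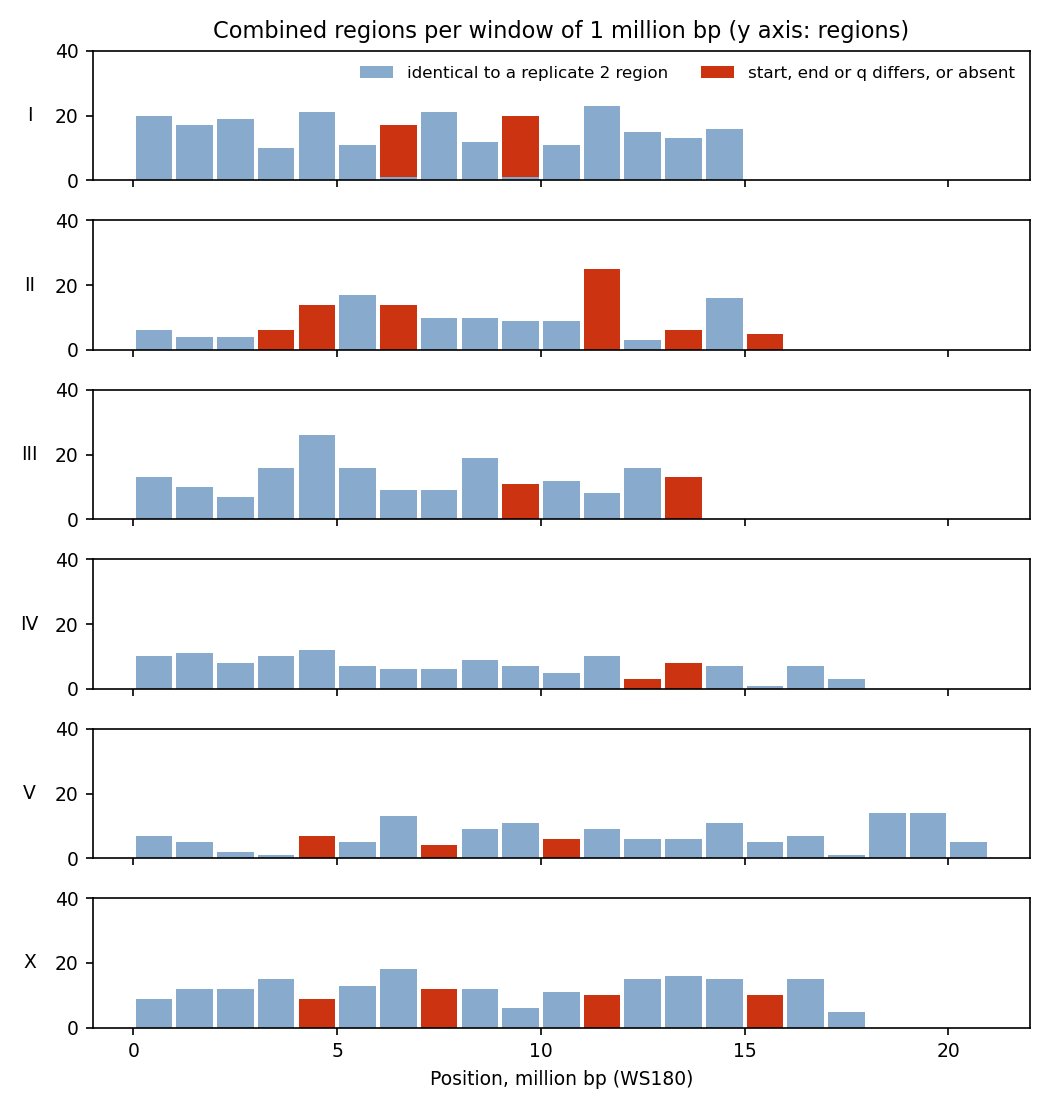
Combined regions in each window of 1000000 bp (y, regions) along each WS180 chromosome (x, Mb): blue for regions with the start, end and q of a replicate 2 region, red for the others. Blue and red fill separate windows except in 2 of 102, both on chromosome I.

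The second comparison asked how the regions were spread over the chromosomes. Chromosome V held fewer UNC-39 regions than its share of the span would give, and chromosomes III and X held more. Chromosome V had 148 combined regions against 228 for its share of the span covered by the lists (ratio 0.65, 95% Wilson interval 0.559 to 0.754; exact two-sided binomial test with Benjamini-Hochberg adjustment over 6 chromosomes, adjusted p = 1.55e-09). In replicate 1 the ratio on V was 0.493 (same exact test, adjusted p = 3.64e-06). Chromosome III had 185 combined regions against 151 (ratio 1.23, exact test, adjusted p = 0.00489), and its ratio was 1.56 in replicate 1 (adjusted p = 0.000529). Chromosome X had 215 against 188 (ratio 1.14, exact test, adjusted p = 0.0445), and its ratio was 1.37 in replicate 1 (adjusted p = 0.0076). For III and X the call was lost among the 541 strongest combined regions (exact test, adjusted p = 0.0653 and 0.0539). Over all alternatives their adjusted p in the exact test ranged from 0.000328 to 0.0653 on III and from 3.37e-08 to 0.0539 on X. Chromosome IV had 130 regions against 188 (ratio 0.692, exact test, adjusted p = 3.34e-06), but the ratio of 0.87 in replicate 1 did not pass the test (adjusted p = 0.335). The ratio on chromosome II was 0.959 (exact test, adjusted p = 0.583). The binomial test takes regions as independent of each other. However, 90 combined regions lay within 2000 bp of the next, against a mean of 31.5 in random placements. The p-values may therefore be too small and the intervals too narrow, which matters most for the call on X. The spans also come from the lists themselves, as they run from the first to the last region. The span of X began at position 410018 and that of I at 3790. True chromosome lengths could move the ratios, and the call on X is close to the threshold.

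On chromosome I the replicate lists differed. The combined list had 246 regions there against 162 for its span (ratio 1.51, 1.35 to 1.69, exact test, adjusted p = 1.12e-10), and replicate 2 had 247 (ratio 1.53, adjusted p = 4.07e-11). Replicate 1 had 36 regions on this chromosome, a ratio of 0.754 (0.552 to 1.02, exact test, adjusted p = 0.106), and the combined regions met by both replicate lists had a ratio of 0.776. Of the replicate 2 regions on chromosome I, 14.6% (10.7 to 19.5%) met a replicate 1 region, against 33.01% (29.9 to 36.3%) on the other chromosomes, which gives an odds ratio of 0.346 (two-sided Fisher's exact test, p = 5.92e-09). The other chromosomes were not alike: the share was 22.4% (16.46 to 29.8%) on V and between 34.7% and 36.2% on II, III, IV and X, and V was not tested against these. The test of chromosome I was chosen after the lists were seen. It also takes regions as independent of each other, so close regions may make its p-value too small.

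**Figure D3:**
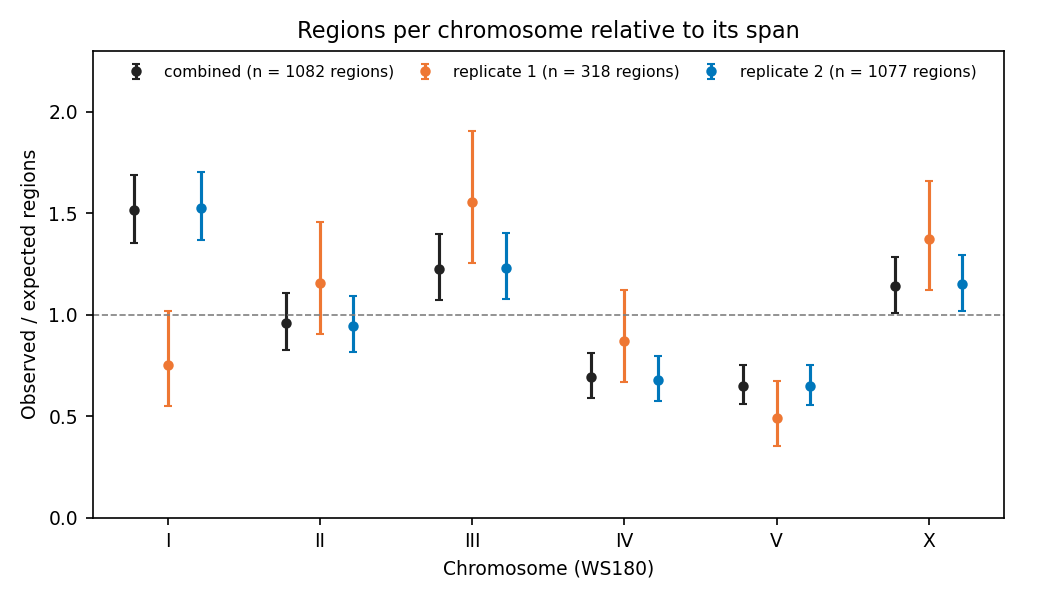
Observed over expected number of regions on each WS180 chromosome for the combined list and both ChIP replicate lists, where the expected number follows the span of the chromosome. Points are ratios, bars 95% Wilson intervals and the dashed line 1; chromosome I lies at 1.51 in the combined list and at 0.754 in replicate 1.

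Along the chromosomes, the combined regions showed no preference for the centre that the test could detect. Each span was divided into 3 equal parts, and the middle parts held 357 of 1082 combined regions, or 32.99% (30.3 to 35.9%; exact two-sided binomial test against 1 in 3 regions, p = 0.822). In replicate 1 the share was 37.4% (32.3 to 42.9%, p = 0.122 by the same exact test). On the autosomes alone it was 39.7% in replicate 1 (96 of 242 regions, 33.7 to 45.9%, exact test, unadjusted p = 0.0406) and 33.6% in the combined list (p = 0.885 by the exact test). No single chromosome passed the adjusted threshold in any of the 3 lists.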

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

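The limit of 50 bp on width and the restriction to windows with identical lists were chosen after the data were seen, and changed no call. Of 57 values under alternatives, over 12 results, 49 were counted as unchanged. Those with a test kept their side of the threshold and, where the test passed, their direction. The makeup of the combined list has no test. Its share with a reciprocal overlap, 26.3%, stayed within the 95% interval of the reported share. Direction was not required where no test passed: the ratio on chromosome II was 0.959 in the combined list and 1.16 in replicate 1. Likewise, the share in the middle parts was 32.99% and 37.4%. The overlap of replicate 1 with replicate 2 ranged from 72.3% (against as many top replicate 2 regions as replicate 1 has) to 98.7% (regions stronger than the median of each list), and its permutation test passed in every setting run. The share of combined regions met by both replicate lists was 52.7% among the 541 strongest, against 28.6% in the whole. Among these 541 the ratios on chromosomes III and X were 1.21 and 1.20 and no longer passed the test; fewer regions were tested. Among the regions in both replicate lists, the ratio on chromosome I fell below 1, to 0.776 (0.568 to 1.05), and that on IV was 0.858, and neither passed the test. With each replicate list in place of the combined list, the ratio ranged from 0.754 to 1.53 on chromosome I and from 0.680 to 0.870 on IV, and the lower value on I and the higher on IV came from replicate 1. With gene number as the expectation, chromosome II passed the test at 0.846. The cause was not tested for II and IV; chromosome I is taken up under the other observations. The ratio on V stayed below 1 and past the threshold in all 7 alternatives. Many alternatives share most of their regions with the main list or with each other, so they are not independent checks. The share in the middle parts of the chromosomes did not pass the test in any alternative run over all chromosomes; over the autosomes alone, replicate 1 gave 39.7% at an unadjusted exact p of 0.0406. The share near transcript starts, the gene lists and the motif gave no value under any setting, as no annotation or genome of the build was at hand. No overlap of the replicates can be had without a replicate. No paired analysis was possible because the input samples had no lists here and the ChIP replicates are a single group. The unknown depth limits what the shorter replicate 1 list can show: absence of a region from it does not show absence of binding.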

Other observations

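The tests of the rows shared between lists, of the score ratio on chromosome I and of the wide region were chosen after their results were seen. Those of the spacing, of the classes of q and of the strongest regions on chromosome I were written down before.

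UNC-39 regions lay close together more often than random placement gave. In the combined list, 90 regions lay within 2000 bp of the next region, against a mean of 31.5 and a range of 15 to 47 in 1000 random placements along the same chromosomes. In replicate 1 the number was 16, against a mean of 2.82 and at most 8. Whether such regions are separate binding sites or parts of the same enriched stretch was not tested. Random placement also does not model where along a chromosome regions can be called. In the combined list there were 74 runs of such close regions, 10 of them with 3 or more. The longest held 7 regions on chromosome I from 7710511 to 7716853, with a smallest q of 4.93e-21, and 3 of the 7 met a replicate 1 region. A run of 4 regions on chromosome X from 16928134 to 16931821 had a smallest q of 9.59e-25, and 3 of these met a replicate 1 region. Another 4 regions lay on X from 6252078 to 6256815, of which 1 met a replicate 1 region. The densest window of 1000000 bp was that from 4000001 to 5000000 on chromosome III, with 26 combined regions.

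The combined and replicate 2 lists had identical rows in blocks. Of 102 windows of 1000000 bp that hold combined regions, 83 held only regions identical in start, end and q to replicate 2, 17 held none, and 2 held both kinds. On 9 grids shifted in equal steps, 22 to 32 windows held both kinds, and 1000 permutations of the identical regions within chromosomes gave at least 66. This is consistent with a calling step run in fixed windows on largely the same reads; in the altered windows the edges of overlapping pairs moved by a median of 3 bp at the start and 4 bp at the end. A combined list called on pooled reads, beside a replicate 2 list from its own reads alone, is argued against: of the 309 combined regions that met a replicate 1 region, 82.5% (77.9 to 86.4%) had exactly the replicate 2 row. Whether the replicate 2 list was itself called on the reads of both replicates cannot be told apart from a deeper replicate 2 library, since either may give the smaller q in 97.7% of shared pairs; the overlap of the replicates is independent evidence only in the second case.

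Chromosome I regions of replicate 2 were seldom found in replicate 1, and chromosome V had the next lowest share, 22.4%, in a difference that was not tested. A lower yield of replicate 1 that acts alike on every chromosome is argued against as the only difference between the lists. Within 5 classes of q in replicate 2, the Mantel-Haenszel odds ratio for chromosome I against the rest was 0.158 (two-sided permutation within classes, p = 0.0002, the smallest possible). In the strongest class, 64.4% of chromosome I regions were found in replicate 1 against 91.2% elsewhere, with 81.0% (17 of 21) on V. The classes rest on q in replicate 2, so a stronger score on chromosome I in that list could also give these values. The test thus does not place the difference in replicate 1. The permutation tests of chromosome I also take regions as independent of each other. Regions near the calling threshold do not account for the excess on chromosome I either, since the ratio was 1.54 (1.32 to 1.79) in the 541 strongest combined regions and 1.49 in the other 541. Where both lists had the region, the ratio of −log10 q in replicate 1 to replicate 2 had a median of 0.497 on chromosome I and 0.634 elsewhere. It was 0.569 on V and 0.624 to 0.650 on II, III, IV and X. The difference of I from the rest was -0.137 (two-sided permutation test, p = 1e-05, the smallest possible). For these shared regions the score on chromosome I was thus relatively weaker in replicate 1 or stronger in replicate 2. Whether this holds along the whole chromosome was not tested. The middle part of I held 18 of 36 replicate 1 regions and 79 of 247 replicate 2 regions, a difference that was not tested. Which list is the unusual one stays open, and no biological explanation was tested, since both replicates belong to one group.

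The region of 23758 bp on chromosome V was 4.96 times as wide as the next and made up 4.42% of the combined length. The strain carries an unc-39 transgene made by bombardment with a plasmid, and unc-39 lies on chromosome V in the gene table used here, so a candidate explanation is copies of the transgene insert that the control did not level out. The edges differed by 11 bp and 29 bp between the replicate lists, 40 bp in sum. The median was 75 bp for the other 310 shared pairs, of which 27.4% had a smaller sum. In bp the shift was thus below the median but not extreme. Shifts were not set against the width of a region, and this region was far wider than the others. A construct could give such edges, but so could broad binding, and these cannot be told apart without the coverage of the inputs, which was not analysed here. The position of unc-39 on WS180 was not available to test whether the region covers it.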
